A study of Caenorhabditis elegans with 2 samples.

How the data were processed

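The data are peak lists from anti-GFP ChIP-seq of ELT-2 in whole L3 hermaphrodites, with biological replicates 1 and 2, per the labels. Both samples form 1 group, so no groups were compared. The p-values come from genes or peaks, not from separate samples, and measure how unlikely a pattern is over the genome of these samples.

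The authors deposited, on the builds ce10 and ce11, a list of peaks together with background for each replicate, a list of the same kind for the pooled replicates, and a list of the peaks that passed IDR, a filter on how well ranks repeat between replicates. A control library entered the peak calling, per the deposited text files, and was not analysed here. The peak caller, the aligner, their versions and the IDR threshold are not given in the sources used here. The deposited signal of each peak is the authors' value against the control, on a scale that depends on the list, and was used only to describe, rank or filter peaks. The deposited −log10 q of each peak was not used to rank, because 95.2% of the IDR-passing peaks shared the highest value of 3.13. The deposited summit offset from the peak start gave each summit position. Most peaks have a fixed width (440 bp for 59.6% of the IDR-passing peaks), so summits rather than edges were used throughout. The pooled list and the list of replicate 2 hold exactly 30000 peaks and that of replicate 1 holds 28033. The IDR-passing list was identical to the 9198 strongest peaks of the pooled list, so taking those peaks in its place changed nothing. Sequencing depth is unknown, since the lists hold no read counts, and how depth limits the weaker peaks could not be assessed. The intervals given cover counting error only.

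The main peak set was the ce11 IDR-passing list. Peaks on the mitochondrial chromosome were left out of all tests and counted separately. The ce10 lists served only as alternatives, without any conversion of coordinates, and the text files were read for provenance only. The genome sequence and the annotation were those of WBcel235 (Ensembl release 115), the same assembly as ce11. A coding gene was called bound if a summit lay in its promoter window, 1000 bp upstream to 500 bp downstream of any annotated transcript 5′ end. In the annotation classes, the promoter window came before exon, intron and intergenic sequence.

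The gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The 13 lists hold 387 symbols, of which 386 matched the annotation, and no gene is on more than 1 list. They cover intestinal structure and transport, digestive proteases and lipases, vitellogenins, endoderm and intestinal transcription factors, innate immune effectors, lipid metabolism, metal and xenobiotic response, germline and meiosis, neuronal function, body wall muscle, pharyngeal muscle, hypodermis and cuticle, and cytosolic ribosomal proteins. The first 7 of the 13 lists were drawn up for the intestine, but not every member is an intestinal gene: the immune list includes the epidermal antimicrobial peptide genes nlp-29, nlp-31, cnc-2 and cnc-4, and the transcription factor list includes hbl-1, which is known from the epidermis, none of them bound. Ribosomal proteins and some genes of the other lists are also active in the intestine. Bound shares were compared by two-sided Fisher's exact tests against all other nuclear coding genes (19973 genes in all), with Benjamini-Hochberg adjustment over lists or over families, and a threshold of 0.05. For odds ratios 0.5 was added to each cell. Genes that share a promoter can share a peak, so distinct peaks are counted beside genes.

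The rule for named genes took elt-2, unc-119 and ges-1, the 10 strongest nuclear peaks by the nearest coding gene, the 2 members with the strongest peak in each list, and the 2 such members in each of the 5 families with the smallest p. All other named genes were chosen after their values were seen.

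Location was compared with 1000 random placements of the summits on the same chromosomes, by a two-sided permutation test. TGATAA on either strand within 100 bp of a summit was compared with windows of equal length centred 500 bp away by a two-sided exact sign test on the peaks in which only the summit or only the flank had the site. Replicates were matched by summits within 100 bp, with 200 bootstrap draws over peaks for the interval of Spearman's rho. Density on X was compared with its share of nuclear length by a two-sided exact binomial test. Shares have 95% exact (Clopper-Pearson) intervals.

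The work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The steps were tested on simulated data. For the gene lists, 400 of 400 sets of 30 genes planted as bound more often, 328 of 400 planted as bound less often (82.0%) and 8 of 400 unchanged sets (2.00%) were called among 19973 genes. The simulated sets were drawn at random, and each gene was bound independently of its neighbours. These rates therefore do not cover families of neighbouring genes that can share peaks. Random summits gave a promoter fold of 0.988 and a TGATAA difference of -0.722 points, and sites planted at 50% of 9000 summits gave 40.0 points where 41.1 were planted. A planted correlation of 0.9 gave a Spearman's rho of 0.887 over 9000 peaks.

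The alternatives were narrower and wider promoter windows, assignment to the nearest gene only, the stronger part of the peaks, genes with promoter windows of their own (11674 genes), each replicate's own strongest peaks, other distances from the summit, the site WGATAR, unbound promoters as the background, other rules for matching replicates, the ce10 lists, and other backgrounds for X. An alternative that rotates the bound status of all genes along the genome, keeping gene order, and one that leaves out the coding genes of the stretch around elt-2 were added after the data were seen.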

Results

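The binding sites of ELT-2 were mapped in whole Caenorhabditis elegans hermaphrodites at the L3 larval stage, 40 hours after synchronization at L1. ELT-2 is the GATA-type transcription factor of the differentiated intestine, and its core site is TGATAA. The animals were of strain OP56, which carries the integrated transgene wgIs56 and expresses ELT-2 with GFP and FLAG at its C-terminus. Chromatin was immunoprecipitated with an antibody against GFP and sequenced (ChIP-seq). Both samples, biological replicates 1 and 2, belonged to 1 group, so no comparison between conditions was possible. The sources describe lists of peaks for each replicate, for the pooled replicates, and for the peaks that passed an irreproducible discovery rate (IDR) filter. The number of sequenced reads is unknown, because peak lists hold no read counts. Coordinates are on ce11, counted from 1.

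Both replicates together show where peaks of the immunoprecipitation of tagged ELT-2 lay in the L3 genome. The IDR-passing list held 9198 peaks, of which 9181 lay on the nuclear chromosomes and 17 on the mitochondrial chromosome. Their signal, the authors' value per peak, ran from 74.97 to 9719 with a median of 203.9. The strongest peak of all lay at chromosome II 2378217 to 2379212, with its summit 885 bp upstream of F16G10.6 (WBGene00017521) in intergenic sequence and 2 TGATAA sites within 100 bp of the summit. It ranked first in the pooled list and in the lists of replicate 1 and replicate 2, with signals of 9719, 4678 and 5013. The next nuclear peaks lay 3865 bp upstream of C08E8.3 on chromosome V (4246, 4 TGATAA sites), 6386 bp upstream of Y37A1A.2 on chromosome IV (4113, 3 sites) and 480 bp upstream of srz-62 on chromosome IV (3796, 6 sites). Among the other 6 of the 10 strongest nuclear peaks, the summit nearest to C52E2.3 was intronic (3455), and those nearest to zig-13 (3277), fbxc-29 (3166), T24E12.13 (3138), ampd-1 (3115) and aagr-2 (2952) were intergenic. Each of the 10 had at least 1 TGATAA within 100 bp of its summit.

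The replicates shared most of their strongest peaks and fewer of the weaker ones. Of the replicates' own lists, which include background, 16503 peaks matched by summit within 100 bp, 58.9% of the 28033 peaks of replicate 1 and 55.01% of the 30000 of replicate 2. Of the 9198 IDR-passing peaks, 8857 (96.3%) had a match in both lists and 10 in neither. That share is not an independent measure of overlap, because the list was made from both replicates together and equals the strongest pooled peaks. Across the 16503 peaks matched between the replicates, log10 signal had a Spearman's rho of 0.899 (95% bootstrap interval 0.894 to 0.903) and a Pearson's r of 0.922. These correlations run across peaks, which are not independent replicates, and 2 samples allow no test. Of the 5000 strongest peaks of replicate 1, 89.2% met one of the 5000 strongest of replicate 2, against 1.08% for randomly placed summits. The share was 76% for the 100 strongest, 84.9% for the 9198 strongest and 64.7% for the 20000 strongest. Anywhere in the other replicate's list, 100% of the 100 strongest of replicate 1 and 99% of those of replicate 2 had a match. Matching by any overlap of 1 bp lowered rho to 0.782.

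Promoters of genes on 6 of the 7 lists drawn up for the intestine were bound more often than those of other genes, the exception being the vitellogenins. A summit lay in the promoter window, 1000 bp upstream to 500 bp downstream of a transcript start, of 23 of 25 digestive proteases and lipases (92.0%) and of 18 of 20 genes for intestinal structure and transport (90.0%), against 26.6% of the other coding genes in each case. Innate immune effectors (27 of 38, 71.1%), lipid metabolism genes (24 of 32, 75%), metal and xenobiotic response genes (23 of 36, 63.9%) and endoderm and intestinal transcription factors (14 of 24, 58.3%) were also bound more often. Cytosolic ribosomal protein genes, which are active in every tissue, reached 53 of 58 (91.4%). Genes of the cuticle and hypodermis (1 of 34), of the germline and meiosis (3 of 35) and of neurons (3 of 35) were bound less often.

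**Figure D1:**
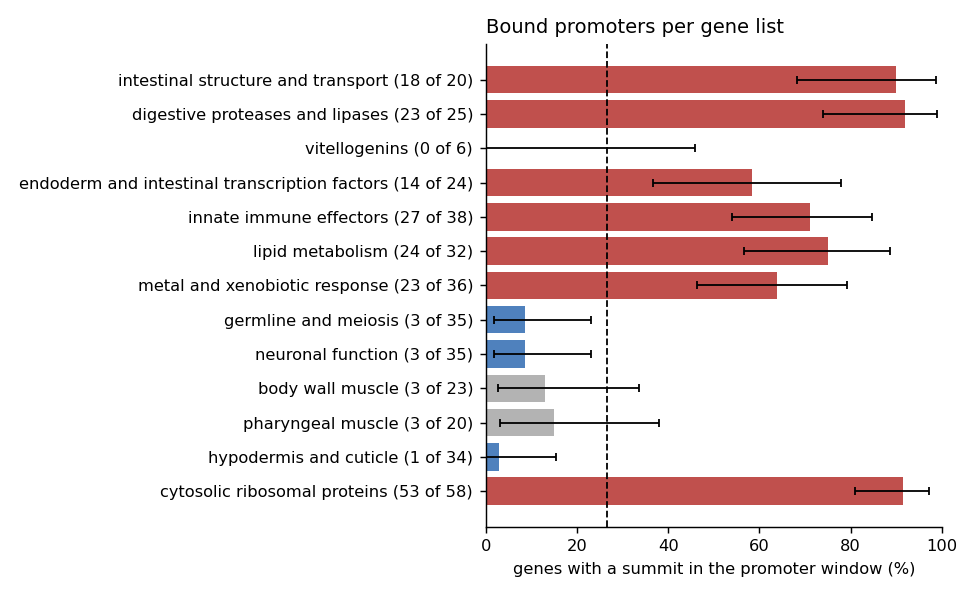
Percent of genes in each of 13 lists with an IDR-passing summit in the promoter window (horizontal axis), with 95% exact binomial intervals as error bars and counts beside the list names; the dashed line is the share of all 19973 coding genes (26.7%), red bars are higher, blue bars lower and grey bars not past an adjusted p of 0.05. Proteases and lipases (92.0%), ribosomal proteins (91.4%) and intestinal structure and transport genes (90.0%) stand highest, and cuticle genes lowest among the bound lists (2.94%).

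In the list of intestinal structure and transport genes, the strongest promoter peaks were those of pept-1 (WBGene00003877), an intestinal peptide transporter, with the summit at X 6456759, 113 bp upstream, and a signal of 1335, and of act-5, the actin of intestinal microvilli, at III 13606302, 236 bp upstream, with 1122. The members without a summit in the window were ges-1 and sucg-1. For ges-1 an IDR-passing summit lay 1132 bp upstream, just outside the window. With a window of 2000 bp upstream to 500 bp downstream, 19 of 20 were bound. Among proteases and lipases, the cathepsin B-like genes cpr-4 (V 6614577, 97 bp upstream, 2544) and cpr-3 (V 15298805, 105 bp upstream, 1803) led, and cpr-2 and lipl-4 had no summit. The odds ratios were 20.4 for structure and transport (two-sided Fisher's exact p = 4.79e-09, adjusted 2.08e-08) and 25.98 for proteases and lipases (exact p = 9.96e-12, adjusted 6.47e-11), with Benjamini-Hochberg adjustment over the 13 lists here and for every list that follows. The protease and lipase odds ratio was 45.5 without replicate 1 (24 of 25) and 13.6 with assignment to the nearest gene only (21 of 25), and 16 of 16 were bound among genes whose window overlaps no other. The largest adjusted exact p of these was 1.39e-08.

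Of the immune effectors, the lysozyme gene lys-8 had the strongest promoter peak (II 5585981, 197 bp upstream, 2356), followed by the saposin-like gene spp-8 (IV 8481509, 155 bp upstream, 1178). In lipid metabolism, the strongest summit was counted to dgat-2 (V 17659408, 895 bp upstream, 2407), although the nearest transcript start was that of fbxa-108, and fat-4, a fatty acid desaturase gene, followed with an intronic summit (IV 9801663, 1332). For metal and xenobiotic genes, the haem transporter gene hrg-1 (X 4009135, intron, 2081) and the metal transporter gene smf-3 (IV 2618769, 100 bp upstream, 1384) led. All 6 of these summits had TGATAA within 100 bp. The odds ratios of the immune, lipid and metal lists were 6.61, 7.96 and 4.81, with adjusted p of 4.14e-08, 4.14e-08 and 6.67e-06 by two-sided Fisher's exact tests. Over the alternatives these odds ratios ran from 6.58 to 20.1, from 5.37 to 18.1 and from 3.68 to 7.44, and no call was lost.

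Endoderm and intestinal transcription factors fell into bound and unbound members. The nuclear receptor gene nhr-8 (IV 7711037, in its 5′ UTR, 1488) and zip-2 (III 833134, intron, 833) carried the strongest peaks, and elt-7, the GATA factor gene that acts beside elt-2, was bound by 2 peaks. No summit lay in the windows of end-1, end-3, med-1 and med-2, which act in the early embryonic endoderm lineage, nor in those of dve-1, mdt-15, hbl-1 and pal-1. The windows of elt-2 and elt-4 held none either, but both genes lie in a stretch of 83.7 kb where no list used here has any summit, so their binding is undetermined. The members named beyond nhr-8, zip-2 and elt-2 were chosen after their values were seen. The odds ratio was 3.81 (two-sided Fisher's exact p = 0.00163, adjusted 0.00264), and 4.70 without the genes of that stretch (14 of 22, adjusted exact p = 0.000558), an alternative added after the stretch was seen. With only the genes whose window overlaps no other coding gene's window, 7 of 15 were bound and the adjusted exact p was 0.0528. None of the 6 vitellogenin genes, which encode yolk proteins made by the adult intestine, had an IDR-passing summit (exact p = 0.352, adjusted 0.352), and 6 genes allow a bound share of up to 45.9% by the 95% exact interval. By the strongest peaks of replicate 1 alone, vit-1 was bound (1 of 6, odds ratio 0.789 against 0.212), and the pooled list had a summit 113 bp upstream of vit-1 at rank 9558, below the IDR-passing 9198.

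Among the lists with few bound members, the germline genes him-8 (signal 204) and fbf-2 (149), the neuronal genes egl-21 (234) and snb-1 (116) and the epidermal GATA factor gene elt-3 (106), the single bound gene of the cuticle list, carried the strongest peaks. The transcript starts nearest to the summits counted to fbf-2 and egl-21 were those of nspg-3 and F01D4.5. The germline and neuronal lists each had an odds ratio of 0.296 (two-sided Fisher's exact p = 0.0123, adjusted 0.0161), and the cuticle list had 0.123 (exact p = 0.000643, adjusted 0.00119). Body wall muscle genes (3 of 23, odds ratio 0.470, adjusted exact p = 0.192), led by unc-112 (367) and unc-60 (240), did not pass the threshold, nor did pharyngeal muscle genes (3 of 20, 0.550, adjusted exact p = 0.342), led by pha-4 (575) and phat-2 (103). The unc-60 peak had no match in the list of replicate 1. The calls of the germline and neuronal lists rested on 3 bound genes each and ended under some alternative settings: the adjusted exact p of the germline list was 0.116 with a window of 500 bp upstream to 200 bp downstream, and that of the neuronal list was 0.0699 without replicate 2. The cuticle call ended with genes whose window overlaps no other (1 of 22, odds ratio 0.2496, adjusted exact p = 0.107).

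The ribosomal protein list had the smallest p of all lists (odds ratio 27.03, two-sided Fisher's exact p = 3.08e-25, adjusted 4.00e-24). Its strongest peaks lay 275 bp upstream of rpl-3 (III 3867579, 1794) and 229 bp upstream of rpl-22 (II 5055387, 1357), and neither summit had TGATAA within 100 bp. The transcript start nearest to the summit counted to rpl-22 was that of ify-1. In all, 53 distinct peaks lay in the windows of the 53 bound ribosomal protein genes, and 31 of these genes were the coding gene nearest to one of their peaks. Assigning each summit only to the nearest gene lowered the list to 33 of 58 (odds ratio 3.74, adjusted exact p = 1.70e-06), and the stronger part of the peaks, defined by the median signal, gave 32 of 58 (7.37). With windows that overlap no other gene's window, 9 of 10 were bound (22.8, adjusted exact p = 2.89e-05).

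Gene families, defined by symbol prefix with at least 20 coding members, were tested without a chosen list. Of 94 families, 24 were bound more often and 33 less often than other genes at an adjusted p below 0.05. The families with the smallest p were the chemoreceptor families str (5 of 193 genes bound) and srh (11 of 220), the ribosomal families rpl (39 of 47) and rps (28 of 31), and the chemoreceptor family srx (1.98% bound, with 2 bound genes). Their adjusted p were 2.17e-17, 2.35e-15, 3.26e-14, 3.43e-12 and 6.21e-10 by two-sided Fisher's exact tests over 94 families. With the nearest gene only, rpl fell to 26 of 47 (odds ratio 3.51 against 12.9) and rps to 17 of 31 (3.43 against 22.5), with adjusted exact p of 0.000163 and 0.00227. All 18 chemoreceptor families tested were bound less often, and together 44 of their 1300 genes had a summit (3.39%, against 28.3% of other genes). In the str, srh and srx families, the 2 members each with the strongest peaks were srh-70 (II 12519052, 1651), srh-2 (V 731498, 1559), str-39 (539), srx-125 (517), str-7 (258) and srx-21 (128). The transcript starts nearest to the summits counted to str-7 and srx-21 were those of cth-1 and fbxa-72. In the rps family, rps-19 (I 9626078, 903) and rps-1 (III 4475658, 700) led, again without TGATAA within 100 bp. The transcript start nearest to the summit counted to rps-19 was that of hsr-9.

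Other families that were bound often included the UDP-glucuronosyltransferase genes ugt (41 of 67, adjusted exact p = 3.61e-08), the translation initiation factor genes eif (18 of 25, 1.90e-05), the vacuolar proton pump genes vha (15 of 20, 5.22e-05) and the nuclear receptor genes nhr (38.7% of 269, 7.47e-05). Collagen genes (col, 11 of 156, adjusted exact p = 1.03e-08) and neuropeptide genes (flp, 0 of 31, 0.000415) were among those bound rarely. The C-type lectin genes clec as a whole were near the background share (67 of 240, 27.9%, adjusted exact p = 0.738), while all 10 on the immune list were bound. With the stronger part of the peaks, 36 families passed in place of 57, and with rotations that keep gene order 53 did: acs, chil, hsp and spp lost their call (adjusted permutation p = 0.0551, 0.0572, 0.0800 and 0.101).

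Summits concentrated at promoters. Of the 9181 nuclear summits, 5297 (57.7%) lay in a promoter window, against 31.7% ± 0.489 (SD over 1000 random placements on the same chromosomes), a fold of 1.82. Exons held 4.65% against 19% (fold 0.245) and introns 13.7% against 24.09% (fold 0.568). Each of these had a two-sided permutation p of 0.002, the smallest that 1000 placements can give. Intergenic sequence held 24.0% against 25.2% (fold 0.953, permutation p = 0.00599), a difference that turned to 1.04 with the window of 500 bp upstream to 200 bp downstream. The median distance from a summit to the nearest coding transcript start was 574 bp, and 70.2% of summits lay upstream of that start. In total, 5323 of 19973 coding genes (26.7%) had a summit in their window, and 1071 of the promoter summits lay in the windows of more than 1 gene.

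TGATAA was frequent at the summits. It lay within 100 bp of 4945 of the 9181 nuclear summits (53.9%), against 19.02% of flanks of equal length centred 500 bp away, a difference of 34.8 percentage points (95% interval 33.6 to 36.1). The site was at the summit alone in 3942 peaks and in the flank alone in 743 (two-sided exact sign test, log10 p = -522). The looser GATA site WGATAR was at 69.6% of summits and 37.7% of flanks (exact sign test, log10 p = -408). The density of TGATAA was 6.33 sites per kb at the summit and 1.11 per kb at 490 bp before it. At points of unbound promoters matched for distance to the transcript start, TGATAA stood at 18.1%.

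**Figure D2:**
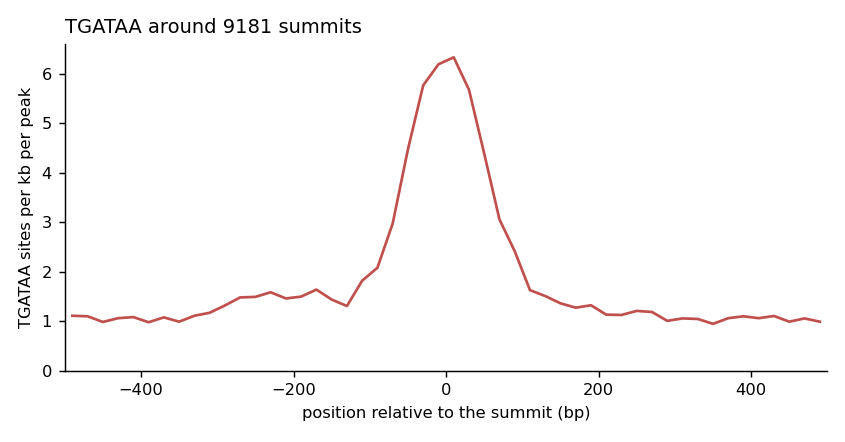
TGATAA sites per kb per peak on either strand (vertical axis) in bins of 20 bp against the position relative to the summit in bp (horizontal axis), over 9181 nuclear IDR-passing summits. The line peaks at 6.33 per kb at the summit and lies near 1.11 per kb at the left edge.

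The share of summits with TGATAA fell with the strength of the peak. It was 80.6% in the strongest of 10 equal bins of peaks by signal and 33.7% in the weakest bin, where flanks stood at 20.8% and 17.5%. The strongest bin had 1.58 sites per summit on average, and 53.5% of its summits had at least 2. In the weakest bin these values were 0.436 and 8.28%. Summits in introns (59.3%) and intergenic sequence (56.6%) carried TGATAA somewhat more often than those in promoter windows (51.3%), and these differences were not tested. Between X (55.2%) and the autosomes (53.5%) the shares were close.

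**Figure D3:**
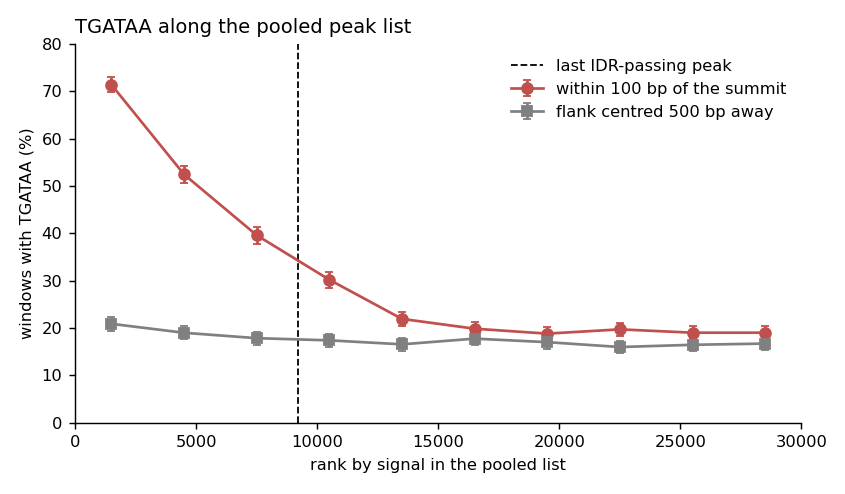
Percent of windows with TGATAA (vertical axis) within 100 bp of pooled summits (red circles) and in flanks centred 500 bp away (grey squares), by rank of signal in the pooled list of 30000 peaks (horizontal axis), in bins of 3000 ranks with 95% intervals as error bars; the dashed line is the last IDR-passing peak. The summit share fell from 71.4% in the first bin to 19.03% in the last, where the flank share was 16.7%.

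The lists differed in their sites. Promoter summits of proteases and lipases (92.9%), immune effectors (89.7%), structure and transport genes (85.2%), metal and xenobiotic genes (76.5%) and lipid metabolism genes (73.7%) carried TGATAA more often than their flanks (exact sign test, log10 p = -6.32, -4.96, -6.32, -5.24 and -4.18 in that order, not adjusted for the number of lists). Summits of endoderm and intestinal transcription factors stood at 44.4% against 33.3% of flanks, and the 95% interval of that difference, -16.7 to 38.9 points, includes 0. Ribosomal protein summits stood at 11.3% against 16.98% of flanks. The 6 intestinal lists with bound members had 141 of 183 summits with TGATAA (77.0%), against 6 of 53 for ribosomal proteins (two-sided Fisher's exact p = 2.45e-18, a test chosen after the shares were seen). The median signal was 418.5 and 254.2 in these sets.

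The X chromosome had the highest density of summits, 111.0 per Mb, followed by II (101.1), III (95.3), V (84.9), I (79.8) and IV (78.7). X held 1967 of the 9181 nuclear summits (21.4%, 95% exact interval 20.6 to 22.3), against 17.7% of the nuclear length, a ratio of 1.21 (two-sided exact binomial p = 3.91e-20). Against its share of coding genes (13.7%) the ratio was 1.57 (exact p = 5.42e-91). Counting only summits in promoter windows (928 of 5297 on X) turned the ratio to the share of nuclear length to 0.991 (exact p = 0.787). The share of promoter summits on X was thus close to its 17.7% share of length and above its 13.7% share of coding genes. The latter difference was not tested, and the ratio of 0.991 holds against length only. Of the coding genes on X, 28.3% were bound, against 31.5% on III and 23.1% on V.

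The genes that the transgene involves and the classical ELT-2 target ges-1 had no IDR-passing summit in their promoter windows. For ges-1, an intestinal esterase gene on chromosome V (1427653 to 1432137, minus strand), the nearest IDR-passing summit lay at V 1433269, 1132 bp upstream of the transcript start and so outside the window. It had a signal of 325.5, rank 2847 and 1 TGATAA. A weak summit of the pooled list, rank 23489, lay 464 bp downstream of the transcript start. For unc-119, the rescue marker gene on chromosome III, the nearest IDR-passing summit lay 53601 bp away and the nearest summit of the pooled list 6592 bp away. The gap around unc-119 was 140.6 kb in the IDR-passing list, where 12 of 9175 gaps, itself included, were at least as long. In the pooled list it was 43.0 kb, with 267 of 29975 gaps, itself included, at least as long. The list of replicate 1 had a weak summit 440 bp upstream of unc-119, with a signal of 11.5, rank 23294 and no match in replicate 2.

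At elt-2 (WBGene00001250, X 10481240 to 10483441, plus strand) the nearest summit of any kind lay 40235 bp upstream. No summit of the pooled list or of either replicate's list lay between X 10441005 and 10524675, a stretch of 83.7 kb with 14 coding genes, among them elt-4, vab-3 and mboa-7. In the pooled list the gap there was 86.6 kb, and 33 of the 29975 gaps between neighbouring summits were at least as long, each such count including the gap itself. In the list of replicate 1 it was 20 of 28020 gaps, in that of replicate 2 46 of 29971, and in the IDR-passing list 94 of 9175. The elt-2 promoter window itself holds 8 TGATAA sites. Whether the lists as used here hold every peak called in this stretch is not known, so no statement on binding at elt-2 can be drawn from them.

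**Figure D4:**
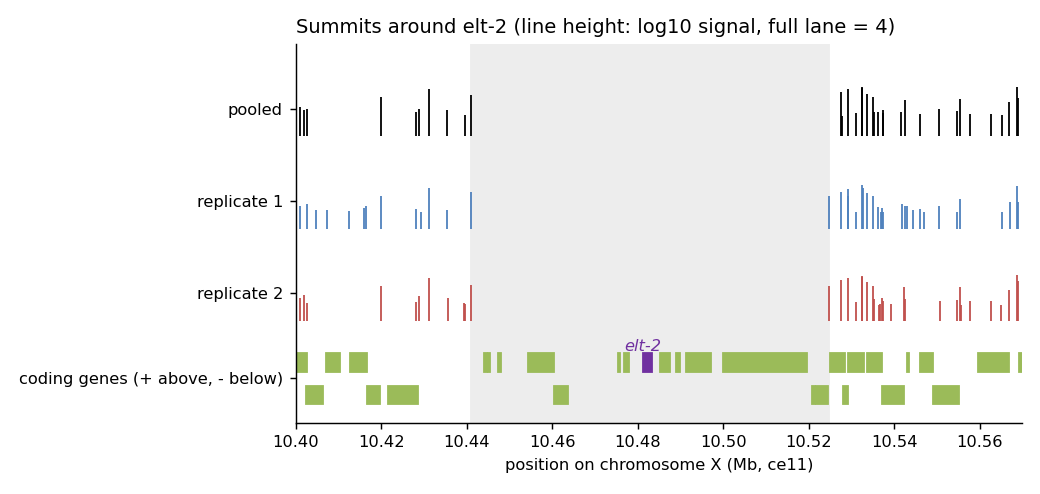
Summits of the pooled, replicate 1 and replicate 2 lists (vertical lines, height on a log10 scale of signal with a full lane at 4) and coding genes (boxes, plus strand above and minus strand below) against the position on chromosome X in Mb (horizontal axis). The grey stretch of 83.7 kb around elt-2 holds no summit of any of the 3 lists, while summits lie on both sides of it.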

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

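No group held enough samples for a search for outlying samples, and both results given here were chosen after the peak lists had been seen.

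The IDR-passing list held 17 peaks on the mitochondrial chromosome, which stood out because they lie outside the nuclear comparisons. That is 1.23 peaks per kb, against 0.0916 on the nuclear chromosomes. The strongest had a signal of 3847 and rank 4, and another had rank 6. TGATAA lay within 100 bp of 4 of the 17 summits (23.5%), against 20.8% of all mitochondrial positions (two-sided exact binomial p = 0.766). Of the 17 peaks, 6 had a match in the list of replicate 1 and 14 in that of replicate 2. Those lists hold 7 and 23 mitochondrial peaks, which limits the matches that replicate 1 could give.

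The pooled peaks below the IDR threshold, which entered no comparison, still carried TGATAA more often at their summits than in their flanks. The shares were 21.2% and 16.8% over 20800 nuclear peaks, a difference of 4.36 points (95% interval 3.61 to 5.11; two-sided exact sign test, log10 p = -29.2). Over the next 9196 nuclear peaks below the threshold the difference was 6.14 points. By rank in the pooled list it was 12.8 points for ranks 9001 to 12000, which include the last IDR-passing peaks. It was 5.37 points for ranks 12001 to 15000, and between 1.80 and 3.73 points in each later bin of 3000 ranks.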

How the results depend on the processing

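The rotation that keeps gene order and the leaving out of genes around elt-2 were chosen after the data were seen, and all other settings were planned. Of 239 alternative values, 220 kept direction and side of the threshold or stayed within the spread, 11 no longer passed the threshold, 6 moved and 2 reversed. The cause was not tested unless given here. With windows of 500 bp upstream to 200 bp downstream, the germline list had an odds ratio of 0.398 (adjusted exact p = 0.116) and the intergenic fold reversed to 1.04 (permutation p = 0.0120), as summits leaving the smaller window become intergenic. With 2000 bp upstream the neuronal list had 0.465 (adjusted exact p = 0.0896), and with the nearest gene only 0.405 (0.0690). With the stronger part of the peaks the germline and neuronal lists each had 0.258 (adjusted exact p = 0.0678 each), the intergenic fold was 0.984 (permutation p = 0.575) and 36 families passed in place of 57. With windows that overlap no other window, which tests fewer genes, 6 lists passed in place of 10: those lost were the transcription factors (3.17, adjusted exact p = 0.0528), germline (0.398, 0.426), neuronal (0.365, 0.139) and cuticle genes (0.2496, 0.107). Leaving out a replicate, the neuronal odds ratio ran from 0.298 to 0.413, and it no longer passed without replicate 2 (adjusted exact p = 0.0699). The replicates' rho was 0.782 with 1 bp of overlap, 0.803 with 50% and 0.911 at IDR-passing summits. Requiring the stronger part of the peaks to lie in the strongest 10% of both replicates' lists left 2557 of 9198 peaks. The X ratio to the share of nuclear length reversed to 0.991 (exact p = 0.787) over promoter summits. Their ratio to the share of coding genes was not computed. Odds ratios that kept their call could still move, for ribosomal proteins (27.03) from 3.74 to 35.4, for the rps family (22.5) from 3.43 to 34.3 and for the str family (0.0793) from 0.0138 to 0.144. The rotation gave 10 list calls, with adjusted permutation p up to 0.0309, and 53 families in place of 57. The strongest pooled peaks were identical to the IDR-passing list. Their values are counted among the 220 but could not differ, so they say nothing about stability. No paired analysis was possible because both samples belong to 1 group.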

Other observations

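The counts of summits at noncoding genes and the tests of 6-base words, of family sites, of vitellogenin distances, of the stretch around elt-2 and of ribosomal against intestinal sites were chosen only after results had been seen, while the test of TGATAA at tRNA genes was not.

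Genes that do not code for protein differed among themselves. Within 200 bp of tRNA genes lay 314 summits, against 26.3 for placements that keep chromosome and promoter status (ratio 11.96). Summits were also in excess at snRNA genes (41, ratio 7.18), snoRNA genes (109, ratio 6.21), lincRNA genes (63, ratio 2.57) and miRNA genes (25, ratio 2.26), and they were scarce at piRNA genes (ratio 0.497) and pseudogenes (ratio 0.461). Each of these 7 had a two-sided permutation p of 0.002, the smallest possible, and an adjusted p of 0.00228 over 8 classes. The ribosomal RNA genes had no summit against 0.823 by chance (permutation p = 0.885). TGATAA stood at 73.9% of piRNA summits (17.4% of their flanks), 63.8% of pseudogene summits (18.5%), 57.1% of lincRNA summits (20.6%) and 52.0% of miRNA summits (12%). At snoRNA summits it stood at 17.4% (14.7% of flanks) and at snRNA summits at 4.88% (31.7%).

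Among 2080 words of 6 bases counted within 50 bp of summits and in flanks, the GATA words CTTATC (29.2% against 3.92%, ratio 7.43) and TGATAA (40.8% against 9.56%, ratio 4.27) led. The 2791 summits without any WGATAR (30.4%) carried GAGAGA at 23.1% against 5.37% (adjusted Fisher's exact p = 1.15e-81) and ACGCAG at 14.7% against 1.58% (adjusted exact p = 1.97e-78). These tests took no account of the pairing of each flank with its summit. Among 2076 words, 656 were called higher and 523 lower at these summits, so a small p alone does not single out a word. The summits without WGATAR lay in promoter windows more often than the others, at 63.6% against 55.1%. Of the 24 families bound more often, 8 had TGATAA at fewer of their promoter summits than other promoter summits did by Fisher's exact test, from rpl (9.76%), rps (10.7%) and dnj (11.1%) through vha (13.3%), mrpl (14.3%), eif (15.8%) and npp (17.6%) to vps (22.7%). Summits of ugt (75.6%), fbxa (77.8%) and math genes (92.0%) had it more often, against 51.3% of all promoter summits. The yolk genes vit-1 and vit-3, without an IDR-passing summit in their windows, had strong IDR-passing peaks farther upstream, at 2082 bp (signal 1695, rank 75) and 3901 bp (1544, rank 102). The nearest such summits of vit-2, vit-4, vit-5 and vit-6 lay 5745 to 8288 bp away, downstream for all but vit-6. Whether any of these peaks belongs to a yolk gene was not tested.

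No summit of any of the 3 lists lay within the 83.7 kb around elt-2. The number of summits within 15000 bp of elt-2 and outside its promoter window was 0, as was the number inside that window. Neither extra copies on the transgene nor binding of ELT-2 to its own promoter could therefore be tested. Background peaks were missing there too, over a stretch with 14 coding genes, elt-2 among them. The promoter window of mboa-7, at the edge, reached past the stretch and held a summit of each replicate's list there. For chance spacing, 0.883% of runs of 14 coding genes on X had no summit of any list in a promoter window (2.13% over all chromosomes). The bound of 1% was set after the stretch was seen, and the value lies close to it. The stretch is not itself such a run, because of the summits in the window of mboa-7, so this test cannot decide on chance spacing. With the 3 lists together, 16 gaps between neighbouring summits were at least as long, this stretch included, and it was the only one of them on X. A lack of sites is argued against by the density of TGATAA, 1.398 per kb, at percentile 95.7 of windows of that length. Removal of the region during processing, or entries not held here, stay open as candidate explanations that were not tested, and no biological explanation was tested.

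Promoters of the 6 lists outside the intestinal set that were bound nonetheless, 53 of 66 of them ribosomal, had TGATAA at 19.1% of 68 summits, 2.94 points above their flanks (95% interval -9.93 to 15.8). This is consistent with recovery of open promoters without an ELT-2 site, although open chromatin was not measured and the 15 summits of the other 5 lists give an interval too wide to decide (20 points, -22.1 to 62.1). The TGATAA share at ribosomal protein summits lay 65.7 points below that at summits of intestinal lists, a difference of -65.7 by Fisher's exact test (two-sided p = 2.45e-18). By the nearest gene, summits that belong to a neighbouring gene could not be told apart from binding at these promoters. Of the 66 bound genes, 41 (62.1%) were the nearest gene of a peak, between the bounds of 50% and 75% set for either outcome. These were 31 of 53 ribosomal genes (58.5%) and 10 of 13 others (76.9%, 95% exact interval 46.2 to 94.96), an interval too wide to decide for the latter. Of the ribosomal genes whose window overlaps no other, 9 of 10 were bound (odds ratio 22.8, adjusted Fisher's exact p = 2.89e-05). For these genes only, that argues against summits of a neighbour's promoter window. Binding of ELT-2 through other proteins or other sites was not tested.

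The peaks at tRNA genes had TGATAA at 23.2% of summits (95% exact interval 18.7 to 28.3), above the flank share of all summits (19.02%), which lies inside the interval, and 2.55 points above their own flanks (95% interval -3.99 to 9.09). Recovery of open chromatin at genes of RNA polymerase III without an ELT-2 site may account for them, but the interval keeps this open. No library without the tagged protein was used here, so background of the immunoprecipitation cannot be separated from binding.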
